A study of Mus musculus with 8 samples.

How the data were processed

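Messenger RNA was profiled in 8 libraries of HSCs sorted from mouse bone marrow, 4 from P5 pups and 4 from mice at 4 weeks of age. Per the labels' protocols, 100 cells were sorted for each library, first and second cDNA strands were made from their RNA, and libraries were prepared with a Nextera XT kit, which does not mark strand. Reads from a gene and from an overlapping antisense partner therefore could not be told apart. Sequencing was on a NextSeq instrument, per the series' design text. Such small inputs need amplification, and these reads carry no molecular identifiers, so intervals and floors cover counting error only. Groups were taken from the ages in the labels, and replicate numbers from the sample titles.

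The deposited files give, for each of 48835 gene rows, raw counts of unique and total reads over exons, introns, exon junctions and the whole gene. Per the file headers the reads had been trimmed. The genome build was mm10 per the submitters' processing notes. The aligner, the counting program, their settings and the annotation are not given in the sources used here. The authors also deposited RPKM values, which were found to be exon reads per kb of exon, scaled to all gene reads (exon and intron), and these were not used for tests. The file of P5 replicate 1 also held the authors' own test of the ages, with its p-value and its corrected p-value for each gene, deposited by the authors and called EDGE per the file headers. Other columns, per the file headers, describe gene models, and range, interquartile range, difference and fold of group means of unnormalised reads, and the latter were not used.

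Expression was taken as total exon reads, the count that the authors' expression column holds. Of the rows, 23457 had an mRNA model. The others had exon length 0 and all their reads listed as intron reads, so they were tested apart, by gene reads. Genes listed on several contigs under numbered names were summed, which departs from counts strictly as deposited: 975 genes with an mRNA model were so merged, leaving 22050. In the file of P5 replicate 4, 24 gene names had been turned into dates and were restored from the row order, since coordinates were the same in all files. Symbols that did not match were looked up among RefSeq synonyms. The files give positions on contigs. Of 35640 genes compared over 89 contigs, 93.5% lay within 1000 bases of the same offset from RefSeq genes on GRCm38.p6, the assembly of mm10, and positions printed here come from that RefSeq table.

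Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filter filterByExpr, quasi-likelihood fits and a model with age alone, over all 8 libraries. Adjusted p-values are Benjamini-Hochberg values over the 12235 genes kept, which held 99.82% of exon reads, and the threshold was 0.05. CPM values are edgeR's normalised exon reads, scaled to the same effective library size. Standard errors of log2 fold changes were derived from the F statistic and are approximate. The common biological coefficient of variation was 0.152. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 23 lists of programs with at least 5 tested members. The 7 marker lists of other cells with as many members were adjusted apart. With few libraries this preset correlation is generous to lists whose genes vary together, so values with an estimated correlation are given beside each call. Sums of marker lists and library measures were compared with two-sided exact permutation tests over 70 splits. They used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

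The tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The rule named 4 kinds of genes. The first were the 8 with the largest log2 fold change in each direction among called genes with no overlap between ages and a mean log2 CPM of at least 4, leaving out unnamed gene models, accession-like names and receptor segments. Next came the 2 members of each program list with the smallest p-value, and up to 2 more in lists with at least 5 called members. The most abundant member and the member with the smallest p-value of each marker list followed, then the sort gate and sex-linked genes. Further genes were named after their values were seen, and the text says so in the parts where they appear. Alternatives were the replicate number as a block, each library left out in turn, no filter or at least 5 CPM in at least 4 libraries, DESeq2 size factors, scaling without globin genes, DESeq2 1.42.0, limma-voom, a log2 fold change of at least 1, an estimated correlation and fry. Alternatives chosen after seeing the data were copies of a gene not summed, uniquely mapped exon reads, exon plus intron reads, intron reads, Y-linked reads as a covariate (present where a library had over 100), and only libraries with such reads.

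On simulated counts for 12124 genes with 200 changed genes, this comparison recovered 52.2% of 1.5-fold, 80.6% of 2-fold and 97.0% of 4-fold changes, with 5% false calls. A list of 30 simulated genes raised 1.5-fold was called, and none of 50 random lists was. The simulated genes varied independently, so the latter says nothing of lists whose genes vary together. Pairs of libraries of an age differed by more than sampling noise, with a chi-square of 4.47 to 15.9 times its degrees of freedom over 10356 genes, so none was a copy of another. For the test of microRNA sites, the longest 3' UTR of each gene was taken from GENCODE M21 transcripts, for 12013 of the 12235 tested genes (98.2%). Genes with the site were compared with genes without it after removing the median of each of 20 bins of UTR length, and against 419 other 8-base words of the same composition. On simulated values a shift of 0.3 was recovered as 0.299. That shift was far above the SD of the control words in the real data (0.0198), so detection of a small shift was not tested.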

Results

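The series measured messenger RNA in haematopoietic stem cells (HSCs) from the bone marrow of C57BL/6 mice, an inbred laboratory strain. HSCs are the rare marrow cells from which all blood lineages arise. They were sorted by flow cytometry as cells with CD150 and EPCR on the surface and without CD48 or lineage markers. The protocol names 100 cells for each library. There were 4 libraries from pups at postnatal day 5 (P5) and 4 from mice at 4 weeks of age. Nothing in the labels says that the libraries of an age came from separate animals. Sex-linked reads, given below, show that P5 replicates 1 and 3 came from other animals than P5 replicates 2 and 4. The p-values thus measure the spread between these samples, which may be technical within those pairs and at 4 weeks. The series text also mentions HSCs cultured for 1 day, and no such sample was analysed here.

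The P5 libraries held 7470777, 6502009, 6142760 and 7072529 exon reads, and the 4-week libraries 6332873, 5775130, 5946150 and 7212446. The difference in exon reads between the ages did not pass the test (two-sided exact permutation p = 0.257 over 70 splits, adjusted p = 0.707 over 11 library measures). Between 14356 and 14802 genes had at least 1 exon read. Reads listed as intron reads took 70.2% ± 2.26 of all gene reads at P5 and 71.8% ± 0.634 at 4 weeks (SD, n = 4 each, exact permutation p = 0.143, adjusted p = 0.629). They include all reads of genes without an mRNA model. Over genes with such a model, introns took 65.6% ± 3.66 at P5 and 68.0% ± 0.791 at 4 weeks (SD, n = 4 each, exact permutation p = 0.171, adjusted p = 0.629). The 50 most abundant genes took 10.6% ± 0.898 of exon reads at P5 and 10.3% ± 0.456 at 4 weeks (SD, n = 4 each). The first principal component of the tested genes carried 48.2% of the variance and separated the ages, with P5 libraries between -35.4 and -27.7 and 4-week libraries between 30.4 and 32.4. The second component carried 14.2% and spread the libraries within each age.

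The comparison of the series asks how HSCs of the newborn period differ from those of the young mouse. HSCs at P5 held more RNA of most genes that mark fetal and neonatal stem cells, and less RNA of most genes for antigen presentation. Interferon-stimulated genes were mostly lower too, though as a list not with an estimated correlation (adjusted p = 0.193 with an estimated correlation). Igf2bp3, an RNA-binding protein of fetal tissues, was 24.99-fold higher at P5, with 57.2 ± 4.08 CPM against 2.22 ± 1.42 (SD, n = 4 each). Gda, guanine deaminase, was 15.0-fold lower, with 5.54 ± 1.39 CPM at P5 against 83.6 ± 15.8 at 4 weeks (SD, n = 4 each). The adhesion receptor subunit Itgal, the globin Hbb-bt and the basement membrane collagen Col18a1 were among the genes higher at P5. Of 12235 genes tested, 977 were higher and 1046 lower at P5 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least a 2-fold change was seen in 323 of the genes higher and 349 of the genes lower at P5. All 4 P5 libraries lay on one side of all 4 4-week libraries for 1830 of the 2023 called genes. That separation held for 21.2% of tested genes, where chance gives 2.9%. Reads of Y-linked genes were present in P5 replicates 2 and 4 and in all 4-week libraries, and P5 replicates 1 and 3 had at most 2 such reads. With the presence of Y-linked reads as a covariate, an alternative chosen after seeing the data, 628 genes were higher and 608 lower, and 1169 of the 2023 calls were kept. In the 6 libraries with Y-linked reads alone, 619 were higher and 638 lower. In both settings age rests on P5 replicates 2 and 4 against the 4-week libraries. Calls lost there may reflect the fewer P5 libraries as well as sex.

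The 8 genes with the largest increase that met the naming rule spanned 7.03-fold to 24.99-fold. Igf2bp3 (chromosome 6, 49085218 to 49215469, positions on GRCm38.p6 here and below) had a log2 fold change of 4.64 (SE 0.281, adjusted p = 2.05e-07). Dlk1, an imprinted membrane protein (chromosome 12, 109452485 to 109463336), had 38.5 ± 18.1 CPM at P5 and 1.81 ± 2.00 at 4 weeks (SD, n = 4 each; log2 fold change 4.42, SE 0.495, adjusted p = 4.51e-05). Of its 45 reads at 4 weeks, 28 were in replicate 3, without which the log2 fold change was 5.43. Col18a1 (chromosome 10, 77052178 to 77166530) was 9.42-fold higher and Itgal (chromosome 7, 127296139 to 127335137) 8.57-fold higher. Slit2, a guidance ligand (chromosome 5, 47981291 to 48307735), was 8.23-fold higher. Ptprb, the vascular endothelial protein tyrosine phosphatase (chromosome 10, 116275502 to 116389538), was 8.03-fold higher. Hbb-bt, an adult beta-globin (chromosome 7, 103812524 to 103813923), had 710 ± 151 CPM at P5 and 96.8 ± 21.0 at 4 weeks (SD, n = 4 each; log2 fold change 2.87, SE 0.165, adjusted p = 1.29e-07). Its near-identical neighbour could share reads with it. Tenm4, a teneurin (chromosome 7, 96171244 to 96911093), was 7.03-fold higher.

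The 8 genes with the largest decrease by the same rule spanned 8.87-fold to 15.0-fold. Gda (chromosome 19, 21391307 to 21472661) had a log2 fold change of -3.91 (SE 0.191, adjusted p = 4.99e-08). The class I MHC genes H2-Q7 (chromosome 17, 35439140 to 35443773) and H2-Q6 (chromosome 17, 35424850 to 35430055) were 12.7-fold and 10.3-fold lower. They are near-identical copies whose reads cannot be told apart with certainty. Sema7a, a membrane-anchored semaphorin (chromosome 9, 57939596 to 57962865), was 11.02-fold lower, with 4.87 ± 2.67 CPM at P5 and 53.7 ± 4.92 at 4 weeks (SD, n = 4 each). Nov, a matricellular protein (chromosome 15, 54745910 to 54753762), was 9.71-fold lower. Plxna4, a semaphorin receptor (chromosome 6, 32144543 to 32588192), was 9.04-fold lower. Bgn, the proteoglycan biglycan (chromosome X, 73483601 to 73495936), was 9.01-fold lower. Enah, an actin regulator (chromosome 1, 181896384 to 182027556), was 8.87-fold lower. All 16 genes kept their calls with the Y-linked covariate. Igf2bp1 and S100a16 had no read in any 4-week library and were at least 208-fold and at least 38.7-fold higher at P5. Akr1c19 and S100a8 had no read in any P5 library and were at least 33.9-fold and at least 22.8-fold lower. These bounds rest on a floor of 3 counts over the group and cover counting error only. S100a16 and Akr1c19 were named after their values were seen. Their counts were low, at 124 and 95 reads in the other age, and that of S100a8 was lower still, at 64. Of the 124, 67 were in P5 replicate 2.

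**Figure D1:**
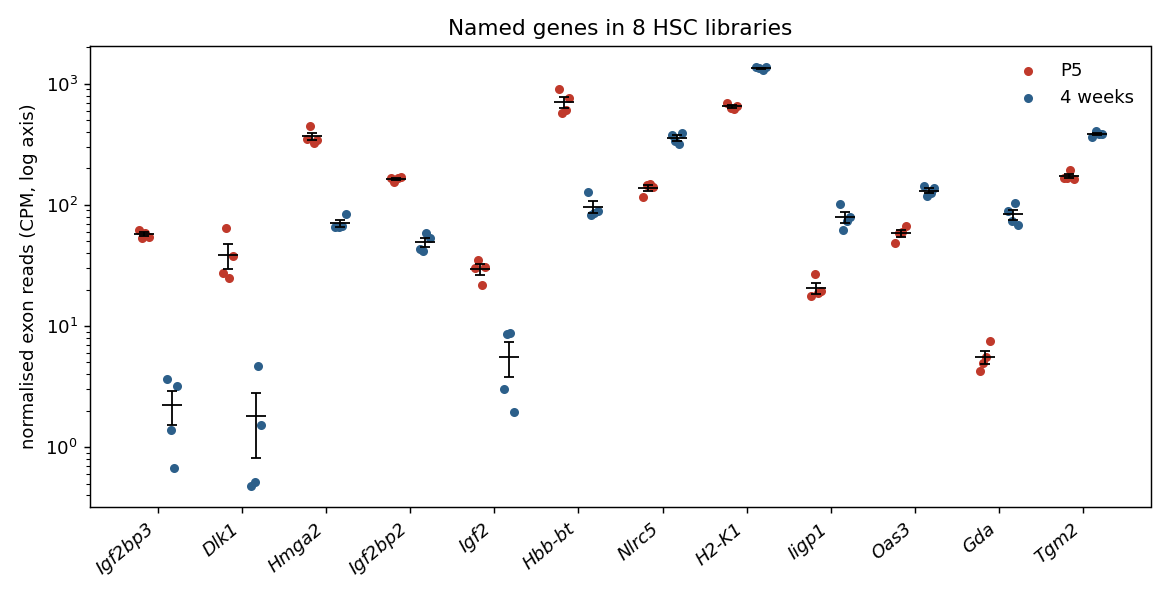
Normalised exon reads in CPM (log axis) of 12 named genes in the 4 P5 (red) and 4 4-week (blue) libraries, with points for libraries, black dashes for means and bars for the standard error of the mean. For all 12 genes the points of the 2 ages do not overlap, and Hbb-bt averages 710 CPM at P5 against 96.8 at 4 weeks.

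Fetal and neonatal HSC genes were higher at P5 nearly throughout. Of 10 tested members, 9 were higher and none was lower, and 9 were higher when adjusted over the list alone. The median log2 fold change was 2.04. Hmga2, a chromatin protein of self-renewing fetal HSCs, had 368 ± 54.2 CPM at P5 and 70.4 ± 8.85 at 4 weeks (SD, n = 4 each; log2 fold change 2.38, SE 0.116, adjusted p = 4.99e-08). Igf2bp2 was 3.35-fold higher (adjusted p = 3.60e-07). The list passed camera's set test (adjusted p = 1.18e-12) and also with an estimated correlation (adjusted p = 0.0108). In the 6 libraries with Y-linked reads, 8 members were higher. The imprinted gene network had 8 of 15 members higher and none lower, and 10 higher and 2 lower when adjusted over the list alone. Igf2, a growth factor expressed from the paternal allele, was 5.37-fold higher, with 29.4 ± 5.64 CPM at P5 against 5.58 ± 3.61 at 4 weeks (SD, n = 4 each). Peg3, a zinc finger protein, was 3.31-fold higher, and Grb10, a receptor adaptor, 1.45-fold higher. The imprinted list was called with the preset correlation (adjusted p = 0.000282), but not with an estimated one (adjusted p = 0.121 with an estimated correlation). With the Y-linked covariate, 5 of its members were higher.

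Genes of antigen presentation were lower at P5 in 20 of 22 tested cases and higher in none. All 22 were lower when adjusted over the list alone, and the median log2 fold change was -1.02. H2-K1, a classical class I heavy chain, had 651 ± 33.98 CPM at P5 and 1345 ± 37.3 at 4 weeks (SD, n = 4 each; log2 fold change -1.05, SE 0.0696, adjusted p = 5.74e-07). Nlrc5, the transactivator of class I genes, was 2.58-fold lower (adjusted p = 1.01e-06). The list passed the set test (adjusted p = 1.37e-22) and also with an estimated correlation (adjusted p = 0.0262). With uniquely mapped exon reads, only 8 of its members could be tested and 7 were lower. Interferon-stimulated genes were lower in 25 of 33 cases and higher in none, with 28 lower when adjusted over the list alone. Iigp1, an immunity-related GTPase, was 3.85-fold lower, and Zbp1, a sensor of Z-form nucleic acids, 10.4-fold lower, with 2.09 ± 0.659 CPM at P5 and 21.9 ± 8.08 at 4 weeks (SD, n = 4 each). Oas3, a sensor of double-stranded RNA, was 2.25-fold lower, and Ifitm3, a restriction factor of viral entry, 1.71-fold lower. The interferon list was called with the preset correlation (adjusted p = 3.90e-15) but not with an estimated one (adjusted p = 0.193 with an estimated correlation). With the Y-linked covariate, 16 of its members and 19 of the antigen presentation list were lower.

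HSC identity genes moved both ways, with 7 of 32 higher and 9 lower at P5, and the same counts when adjusted over the list alone. Ctnnal1, an alpha-catulin marker of HSCs, was 2.18-fold higher. Ly6a, which encodes the surface antigen Sca-1, was 2.90-fold lower (adjusted p = 1.49e-05). Tgm2, a transglutaminase, was 2.23-fold lower and Sult1a1, a sulfotransferase, 6.28-fold lower. The list was not called (adjusted p = 0.12), but some alternatives called it lower, among them fry (adjusted p = 0.0412). Unlike camera, fry tests a list against no change and not against the other genes, so it answers a different question. Among cell cycle inhibitors and quiescence genes, 5 of 21 were higher and 3 lower (6 and 3 adjusted over the list alone). Camera gave adjusted p = 0.12 for the list, and fry, against no change, adjusted p = 0.03. Gfi1, a repressor that restrains HSC proliferation, was 2.15-fold higher, and Cdkn1a, the inhibitor p21, 2.94-fold higher, a call lost with uniquely mapped reads. Ccnd1, cyclin D1, was 2.13-fold higher, and its partner kinase gene Cdk6 was 1.43-fold lower.

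Few cell division genes passed the test gene by gene, though most leaned higher at P5. Of 40 genes of G2/M and mitosis, 1 was higher and none lower, also when adjusted over the list alone, and 7 had an unadjusted p under 0.05. By sign alone, 38 were higher and 2 lower. The called gene was Cenpa, the centromeric histone variant, at 55.2 ± 13.7 CPM against 25.7 ± 8.97 (SD, n = 4 each; log2 fold change 1.10, adjusted p = 0.00571). Cdk1, the mitotic kinase, had a log2 fold change of 0.65 (SE 0.227, adjusted p = 0.0698). The list was called with the preset correlation (adjusted p = 0.00277), but its members vary together, and adjusted p = 0.818 with an estimated correlation. Single libraries moved this result. Without P5 replicate 2, 14 members were higher, without P5 replicate 1 or 4-week replicate 3 the list was not called (adjusted p = 0.101 and 0.123), and with the Y-linked covariate none was and the list median fell from 0.37 to 0.016 on the log2 scale. Of 40 genes of DNA replication none was higher and 1 was lower (also adjusted over the list alone), Chaf1b, a histone chaperone subunit, by 1.44-fold, and Pola1, a DNA polymerase subunit, had a log2 fold change of -0.41 (adjusted p = 0.14). By sign alone, 30 members were higher and 10 lower. The list was not called (adjusted p = 0.223), though it was without P5 replicate 2 or 4-week replicate 2. Of 45 replication-dependent histone genes, 1 was lower and none higher (also adjusted over the list alone), Hist1h2bc by 1.79-fold, a call lost with uniquely mapped reads. Hist1h3f had a log2 fold change of 0.89 (adjusted p = 0.0754), and the list was not called (adjusted p = 0.111), though some alternatives called it higher, among them limma-voom (adjusted p = 0.0449). Histone genes share sequence with their copies, so both values are uncertain.

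Cytosolic ribosomal protein genes were called as a list (adjusted p = 4.04e-07), but not with an estimated correlation (adjusted p = 0.77 with an estimated correlation). Of 79 members, 12 were higher at P5 and 1 lower, the same as adjusted over the list alone. Rps13, Rps23, Rps26 and Rplp0 were 1.35-fold, 1.78-fold, 1.55-fold and 1.34-fold higher, and these genes have many processed pseudogenes that could share reads. Without 4-week replicate 1, 3 were higher, and with the Y-linked covariate 2 were. P5 replicate 1 had the lowest intron share (60.1% over genes with an mRNA model) and the highest rRNA share (7.32%). This library held the highest sum of the list. Without it 6 members were higher and the list median fell from 0.21 to 0.0797. Nuclear genes of oxidative phosphorylation had 4 of 71 members higher and none lower, and none either way when adjusted over the list alone. Ndufv3, a complex I subunit, was 1.43-fold higher and Uqcrc1, a complex III subunit, 1.33-fold higher. The list was called with the preset correlation (adjusted p = 0.00254) and had adjusted p = 0.77 with an estimated correlation. With the Y-linked covariate none of its members was called, nor was the list (set test adjusted p = 0.345). The list was not called with exon plus intron reads either (adjusted p = 0.14), and leaned lower with intron reads (adjusted p = 0.352). Leaving out single libraries gave 1 to 8 members higher, and without P5 replicate 1 the median fell from 0.138 to 0.0467 and the list was not called (adjusted p = 0.101). Cholesterol synthesis had 3 of 23 members higher and none lower, as over the list alone. They included Hmgcs1, the cytosolic HMG-CoA synthase, at 1.74-fold, and Fdps, farnesyl diphosphate synthase, at 1.74-fold. This list too was called with the preset correlation (adjusted p = 0.0367) and had adjusted p = 0.77 with an estimated correlation, and with the Y-linked covariate none of its members was called. Nor was the list called without P5 replicate 1, 3 or 4 or 4-week replicate 3 (adjusted p = 0.101, 0.0847, 0.0843 and 0.179). Its call was also lost with the Y-linked covariate, DESeq2 and exon plus intron reads (set test adjusted p = 0.347, 0.0707 and 0.274), among other settings.

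Other metabolic lists were not called. Glycolysis had 1 of 23 members higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.792). Gapdh was 1.82-fold higher, a call lost with uniquely mapped reads, and the glucose transporter gene Slc2a3 1.37-fold lower. Of 25 genes of pyruvate dehydrogenase and the TCA cycle, edgeR called none, over all genes or over the list alone. There 3 had an unadjusted p under 0.05, DESeq2 called 2 and limma called none (set test adjusted p = 0.357). Citrate synthase, Cs, had a log2 fold change of 0.30 (adjusted p = 0.0548), and Sdhd, a subunit of succinate dehydrogenase, 0.26 (adjusted p = 0.0691). Fatty acid oxidation had 2 of 22 members higher and 1 lower, or 2 higher and none lower adjusted over the list alone (adjusted p = 0.291), with Echs1 and Acads 1.38-fold and 1.36-fold higher. With the Y-linked covariate neither was called, nor without P5 replicate 1 or 4-week replicate 2. Acetyl-CoA supply and fatty acid synthesis had 2 of 16 members higher and 3 lower, as over the list alone (adjusted p = 0.835). Its median of 0.0061 and its mean of -0.30 differed in sign. Acss2, Acacb and Me1 were 1.58-fold, 1.63-fold and 4.71-fold lower, and Elovl6, a fatty acid elongase, 1.31-fold higher. Antioxidant defence had 3 of 24 members higher and 6 lower (4 and 8 adjusted over the list alone; adjusted p = 0.43), with 1 higher without P5 replicate 1 or 4-week replicate 1, 3 or 4. Hmox1, haem oxygenase 1, was 5.06-fold lower, and Gclm and Gclc, the subunits of the glutathione synthesis enzyme, were 1.66-fold and 1.36-fold lower. Gpx1, a glutathione peroxidase, was 1.39-fold higher. Ribosome biogenesis had none of 32 higher and 2 lower, as over the list alone (adjusted p = 0.223), namely Polr1b at 1.37-fold and the transcription factor Myc at 1.56-fold. Autophagy and lysosome had none of 29 higher and 2 lower (1 adjusted over the list alone; adjusted p = 0.494), Lamp2 at 1.25-fold and Hexa at 1.29-fold, a call kept only without 4-week replicate 3 when single libraries were left out, and its median of 0.0091 and mean of -0.037 differed in sign.

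Among called adhesion and signalling genes, more were higher than lower. Niche retention and adhesion had 9 of 24 members higher and 1 lower (10 and 1 adjusted over the list alone). By sign alone, 14 members of this list were higher and 10 lower, with a median log2 fold change of 0.094. Itgal and Itgb2, which together form the integrin LFA-1, were 8.57-fold and 1.93-fold higher, and Cd44, the hyaluronan receptor, was 1.64-fold higher. Ptger4, a prostaglandin E2 receptor, was 2.22-fold lower. The list was called (adjusted p = 0.0114), with adjusted p = 0.388 with an estimated correlation. TGF-beta, BMP and Notch signalling had 10 of 25 members higher and 2 lower (10 and 3 adjusted over the list alone). Tgfbr2 was 1.62-fold higher and Notch1 1.39-fold higher, while the co-receptor Tgfbr3 was 1.41-fold lower. Smad7, an inhibitor of the TGF-beta pathway, was 2.65-fold higher. The members go both with and against signalling. The list was called (adjusted p = 0.00631), with adjusted p = 0.11 with an estimated correlation, and 4 members were higher with the Y-linked covariate and 5 without 4-week replicate 1, 3 or 4. Immediate early and dissociation-response genes had 6 of 21 members higher and 2 lower (8 and 3 adjusted over the list alone) and were not called (adjusted p = 0.0523). Several alternatives called the list higher, with adjusted p = 3.37e-05 with the Y-linked covariate. Klf2, Fosl2 and Ier3 were 3.45-fold, 1.73-fold and 1.63-fold higher, and Jun was 2.02-fold lower. The call for Ier3 was lost with uniquely mapped reads. Of p53 target genes, 4 of 21 were higher and 2 lower (4 and 3 adjusted over the list alone; adjusted p = 0.108, with the Y-linked covariate 0.0396), and none was lower without P5 replicate 3 or 4-week replicate 1 or 4. In this and other lists, counts of a few called members often moved by over 1.5 times when 1 library was left out. Plk2, Sesn1 and Zmat3 were 3.16-fold, 1.84-fold and 1.99-fold higher.

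**Figure D2:**
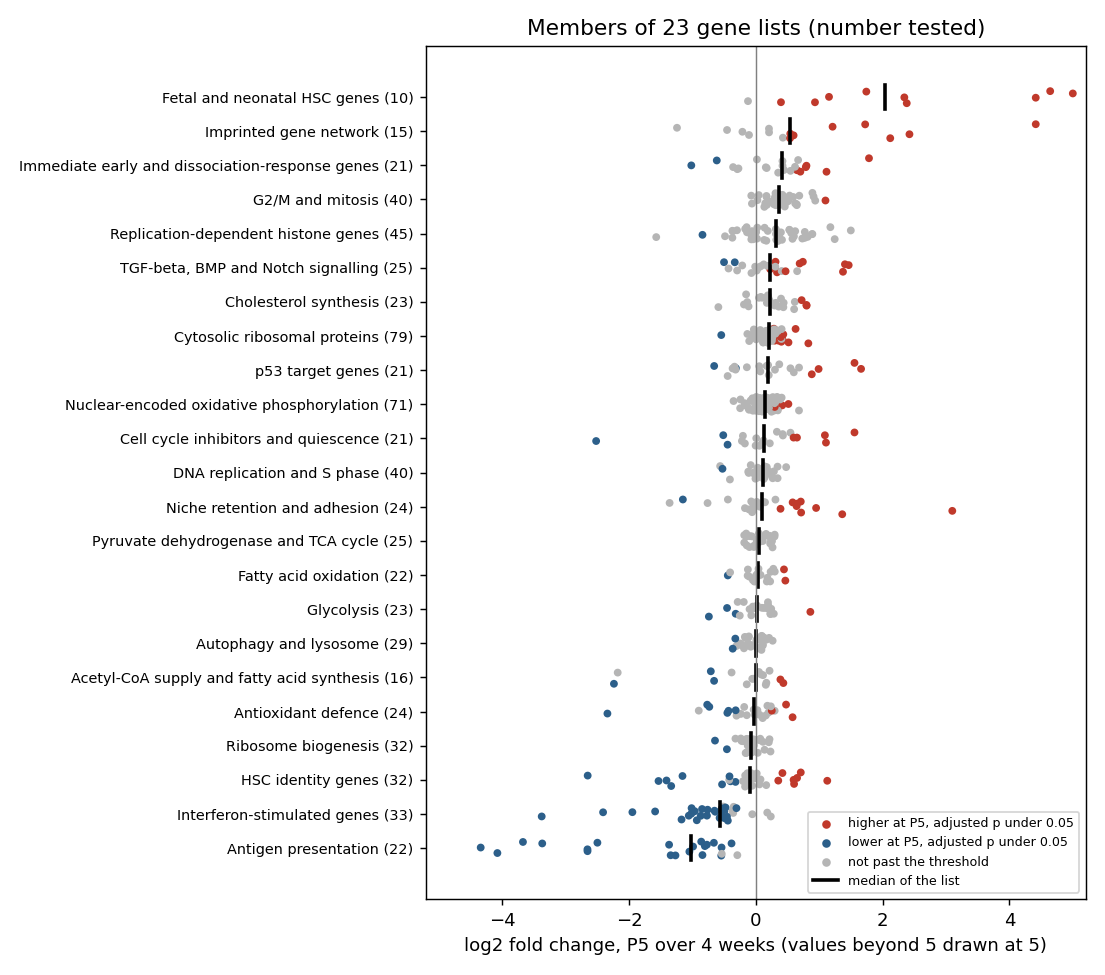
Log2 fold change of each tested member (points) of 23 gene lists, P5 over 4 weeks, with the median of each list as a black bar and colours for members past adjusted p 0.05. The lists of fetal and neonatal genes (median 2.04) and of antigen presentation (median -1.02) lie at the 2 ends.

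The genes of the sort gate did not pass the test. Slamf1, which encodes CD150, had 33.8 ± 4.69 CPM at P5 and 36.6 ± 4.40 at 4 weeks (SD, n = 4 each; adjusted p = 0.618). Procr, which encodes EPCR, had 55.0 ± 7.996 and 57.1 ± 8.03 CPM (SD, n = 4 each; adjusted p = 0.825), and Cd48 had 4.98 ± 3.57 and 5.10 ± 2.66 CPM (SD, n = 4 each; adjusted p = 0.963). Marker lists of other blood cells differed between the ages in part. The multipotent and lymphoid-primed progenitor list was called higher at P5 (adjusted p = 0.0208), with adjusted p = 0.29 with an estimated correlation. It had 5 of 11 members higher and none lower (6 adjusted over the list alone), among them Lsp1 at 1.82-fold and Notch1. Its summed level was 1193 ± 78.7 CPM at P5 and 873 ± 75.3 at 4 weeks (SD, n = 4 each; exact permutation p = 0.0286, the smallest that 70 splits allow, adjusted p = 0.0714 over 10 lists). The endothelial list was also called higher (adjusted p = 0.0322), with adjusted p = 0.29 with an estimated correlation, and had 4 of 10 members higher and none lower (as over the list alone), with 2 higher without 4-week replicate 3 or 4. Ptprb was among them, and the most abundant member, Eng, had a log2 fold change of -0.16 (adjusted p = 0.14). The difference in its summed level did not pass the test (exact permutation p = 0.543, adjusted p = 0.603).

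The megakaryocyte and platelet list had 2 of 15 members higher and 4 lower (2 and 5 adjusted over the list alone; adjusted p = 0.261). Itgb3, an integrin of platelets, was 7.89-fold lower at P5, and Vwf, von Willebrand factor, had a log2 fold change of -0.16 (adjusted p = 0.396). The list summed to 744 ± 63.2 CPM at P5 and 932 ± 51.3 at 4 weeks (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0714). The erythroid list had 1 of 7 members higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.458), and its median of -0.098 and mean of 0.34 differed in sign. Besides Hbb-bt, Car2, carbonic anhydrase 2, was 1.25-fold lower, a call lost without P5 replicate 3 or 4 or 4-week replicate 2, 3 or 4. The erythroid list summed to 1359 ± 182 CPM at P5 and 914 ± 125 at 4 weeks (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0714). Hbb-bt alone, at 710 against 96.8 CPM, exceeded that difference, so the other members together summed to less at P5. The monocyte and macrophage list had 3 of 7 members higher and none lower (as over the list alone; adjusted p = 0.213), with Cd68 2.11-fold higher and Lyz2, lysozyme, at a log2 fold change of 0.12 (adjusted p = 0.363). Without P5 replicate 2, 1 member was higher and the list median fell from 1.08 to 0.064. The neutrophil list had 2 of 5 members higher and 1 lower (as over the list alone; adjusted p = 0.912). Gstm1 had a log2 fold change of -0.24 (adjusted p = 0.201), and the list mean was -0.62 with a median of 0.016. The stromal list had 1 of 5 higher and 1 lower (as over the list alone; adjusted p = 0.422), with Pdgfrb 3.26-fold lower and Col1a2 at a log2 fold change of 0.87 (adjusted p = 0.192). B cell, T and NK cell, and mast cell and basophil lists had 1, 4 and 2 tested members, too few for the set test. The B cell list summed to 42.5 ± 7.39 CPM at P5 and 23.4 ± 2.52 at 4 weeks (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0714). The sums of the T and NK cell list and the mast cell and basophil list did not pass this test (adjusted p = 0.393 for each). Cd79b was 1.83-fold higher, Nkg7 4.28-fold lower and Hdc, histidine decarboxylase, 12.5-fold higher at P5. Of the 13 Hdc reads at 4 weeks, 10 were in replicate 3, so that fold is uncertain. Lck and Il6ra had log2 fold changes of 0.034 (adjusted p = 0.94) and 0.20 (adjusted p = 0.615).

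**Figure D3:**
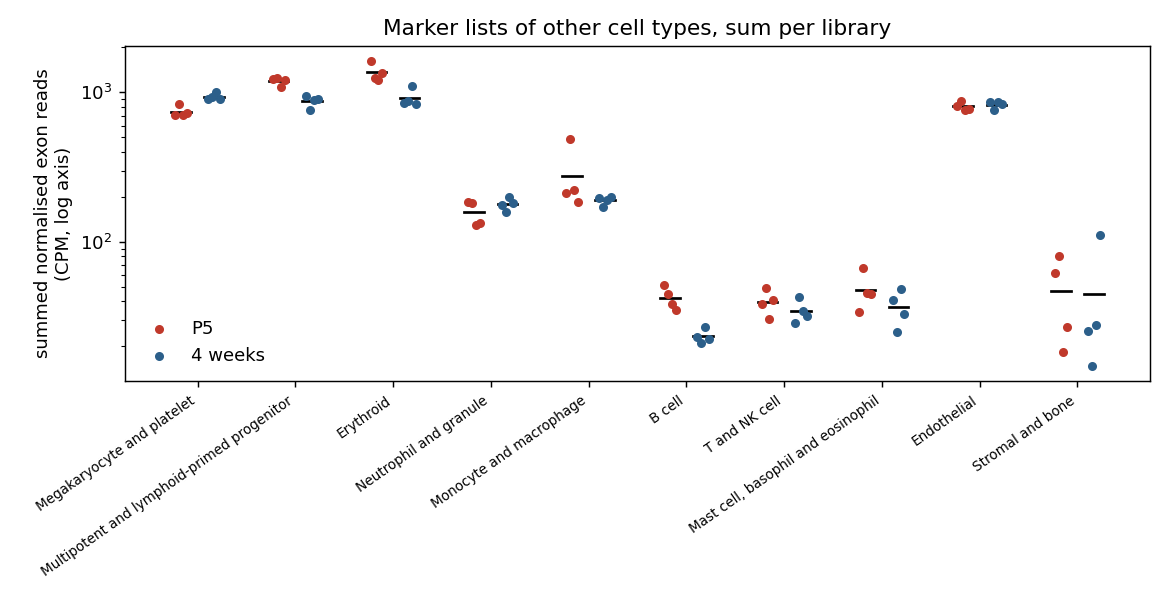
Summed normalised exon reads in CPM (log axis) of the marker lists of 10 other cell types in each P5 (red) and 4-week (blue) library, with black bars for means. P5 replicate 2 stands above the other P5 libraries for the monocyte and macrophage list, at 489 CPM against 184 to 223.

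The sex of the mice is not in the labels. Xist, the RNA of the inactive X chromosome, had 1329 and 1940 reads over its gene in P5 replicates 1 and 3, and at most 6 in each of the other libraries. The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y summed to between 1532 and 2293 exon reads in P5 replicates 2 and 4 and the 4-week libraries, and to 2 and 0 in P5 replicates 1 and 3. None of the 4 passed the test between ages, with log2 fold changes of -0.89, -0.84, -0.91 and -1.08 and adjusted p-values between 0.422 and 0.571 by edgeR. By limma all 4 passed. Libraries without Y-linked reads were thus found at P5 only, and age could be compared within the libraries that have them, but not within those that do not.

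The authors' deposited table of their own test held 1826 rows past its corrected p of 0.05, of which 865 were higher at P5 and 961 at 4 weeks. Of its rows that matched a gene tested here, 1492 were past that threshold. Both tests called 1430 of them, all 1430 in the same direction.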

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

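Tests written after the result was seen were those of the alpha-globin reads, of the depth of P5 replicate 2, of the mature blood cell lists and of the members that are not H2 genes. The uniquely mapped reads and the Y-linked covariate were also chosen after seeing the data, as were genes named here and not in the comparison of ages. Samples were screened for standing far from the other 3 of their age in 276 groups of values, where chance flags about 1 in 20, or 13.8, and 21 stood apart.

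Of the 35 ways to split the 8 libraries into 4 and 4, 1, the real one, gave as many called genes. It gave 2023 and the highest of the other splits gave 1. This permutation p of 0.0286 is the smallest that 35 splits allow, so it argues against chance for the number of genes but does not exclude it. The size of the gap adds little, because every other split mixes the ages, which raises the spread within its groups. For the number of gene lists called with the preset correlation, chance stays open. The real split gave 10 lists, 16 of the 35 splits gave at least as many, and the highest of the other splits gave 14. The lists whose median log2 fold change was larger in the real split than in every other split were the fetal and neonatal, imprinted, interferon, antigen presentation, and TGF-beta, BMP and Notch lists. That gives each a permutation p of 0.0286, the smallest that the splits allow, and an adjusted p of 0.132 over 23 lists, so none passes this test after adjustment.

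P5 replicate 2 held 489 CPM of the monocyte and macrophage list, where the other P5 libraries held 184 to 223, and 158 CPM of Csf1r, where the others held 3.53 to 7.92. Csf1r was called higher at P5 (log2 fold change 3.57, adjusted p = 0.0366), and without this library its value was 0.59 (adjusted p = 0.314, the alternatives giving 0.00525 to 0.404). Depth was argued against, since the library had 0.87 times the exon reads of the deepest other P5 library. RNA of macrophages in that library may be a source, but cannot be told apart from HSCs with such RNA. Of the 21 detected genes of a second macrophage list, 10 (47.6%) were over 2 times higher than in any other P5 library. That fell short of the 50% set in advance. By the same measure within each age, no other library had more than 3 such genes. Of the 21, 14 averaged at least 1 CPM at 4 weeks. Trem2, Cx3cr1 and Fcgr3 were among the 10 (4.66, 64.3 and 9.64 CPM), while Hmox1 was not (2.18 CPM). Nor were Apoe and Sepp1 (181 and 282 CPM). These reached 137 and 257 CPM in another P5 library, so a small share of macrophage RNA would not show in them. The gate on lineage markers should remove mature macrophages.

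Hbb-bt was higher at P5 by 2.87 on the log2 scale, and 4-week replicate 1 stood apart at 128 CPM against 83.1 to 89.6. RNA of red cell precursors was argued against, because alpha-globin reads came to at most 0.00212 of the Hbb-bt reads in a P5 library, and Alas2 had no read in any P5 library. Reads shared between beta-globin copies were argued against by a value of 2.70 with uniquely mapped reads. A difference in the sex of the mice was argued against as the whole cause by 2.78 with the Y-linked covariate. Reads at this locus that come from another unannotated transcript, and age itself, stay open and untested.

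Interferon and antigen presentation genes were lower at P5, with a median log2 fold change of -0.77 over both lists. A difference in sex was argued against as the whole cause, since the median was -0.77 (-0.7664) with the Y-linked covariate. The 43 tested members of both lists that are not H2 genes had a median of -0.64 (quartiles -0.99 and -0.46). Of these, 33 were of the interferon list, which holds no MHC gene and could not share such reads. This median therefore says little of the antigen presentation list. Reads shared between MHC copies cannot be told apart from a change in RNA for the H2 genes. Uniquely mapped reads gave a median of -1.11 for the antigen presentation list and left only 8 of 22 members to test. RNA of mature immune cells in the 4-week libraries cannot be told apart from a change in HSCs either, although the gate should remove such cells. At 4 weeks, 0 of the 5 mature blood cell lists summed to at least 1.5 times the P5 level. The ratios were 1.13, 0.685, 0.551, 0.866 and 0.768 for neutrophils, macrophages, B cells, T and NK cells, and mast cells. P5 replicate 2 (489 CPM) lowered the macrophage ratio. The other P5 libraries held 184 to 223 CPM of that list, and the 4-week libraries 172 to 201. The sums also rest on genes with a high level at P5, such as Lyz2 (172 CPM) and Gstm1 (123 CPM), which would hide a small share. Single markers went both ways (Nkg7 and S100a8 lower at P5, Cd79b and Cd68 higher). So did the second macrophage list. Cd163 (18.9 against at most 4.85 CPM), Hmox1, Siglec1 and Slc40a1 averaged more at 4 weeks than in any P5 library. Apoe, Sepp1, Cfp and Dab2 averaged less at 4 weeks than in P5 replicate 2 and in another P5 library. The biological difference that the design names, age, stays open and is consistent with these values, as do housing and microbial exposure that come with age, and none of these was tested.

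The other values that stood apart are given without explanation. P5 replicate 1 had 66.8% of gene reads listed as intron reads, where the other P5 libraries had 71.0% to 71.7%. This share counts all reads of genes without an mRNA model. P5 replicate 1 also had 45.3 CPM of Gapdh (others 37.5 to 38.4), 203 CPM of Uqcrc1 (143 to 153) and 10.2 CPM of Cd74 (7.33 to 7.76). P5 replicate 2 also had 838 CPM of the megakaryocyte and platelet list (others 706 to 727), 154 CPM of Igf2bp2 (167 to 170), 186 CPM of Tgfbr2 (160 to 163), 172 CPM of Smad7 (87.9 to 90.5) and 331 CPM of Vwf (244 to 252). P5 replicate 3 had 196 CPM of Tgm2 (165 to 166), and P5 replicate 4 had 114 CPM of Ccnd1 (71.3 to 76.9). In the 4-week libraries, replicate 2 had 48.9 CPM of Nov (others 31.6 to 34.3) and 165 CPM of Pola1 (97.8 to 102). Replicate 3 had 1100 CPM of the erythroid list (836 to 870) and 0.168 CPM of Cdh5, a single read where the others had 0. Replicate 4 had 112 CPM of the stromal list (14.8 to 27.8), 20.2 CPM of Itgal (8.37 to 9.31) and 83.7 CPM of Hmga2 (65.1 to 67.0).

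Outside the main measurement, genes without an mRNA model held differences of their own. Of 2775 such genes tested by gene reads with edgeR, 136 were higher and 138 lower at P5.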

How the results depend on the processing

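The intron reads, exon plus intron reads, uniquely mapped reads, copies not summed and Y-linked settings were chosen after seeing the data. No called gene changed direction in the alternatives fixed before the data were seen; 1 did with uniquely mapped reads, 21 with exon plus intron reads and 169 with intron reads, of which 4 were called. Leaving out each library gave 702 to 985 genes higher at P5, 795 to 1069 lower, 6 to 10 lists higher and 2 to 3 lists lower. The lowest gene counts came without 4-week replicates 4 and 1. The highest came without 4-week replicate 2 (985 higher) and without P5 replicate 2 (1069 lower), above those with all libraries (977 and 1046). The counts of genes fell outside 1.5 times with a log2 fold change of at least 1 (323 higher, 349 lower, by construction), with the Y-linked covariate (628 higher, 608 lower), in the 6 libraries with Y-linked reads (619 higher, 638 lower) and, for genes higher, with the replicate block (577 higher, 723 lower). The fit of 6 has fewer libraries. With the covariate, age likewise rests on P5 replicates 2 and 4 alone, since libraries without Y-linked reads were found at P5 only. Both settings thus compare fewer P5 libraries. An estimated correlation left 1 list higher and 1 lower, and intron reads 4 lists higher; the cause of the latter was not tested. The remaining settings gave 890 to 1281 genes higher and 959 to 1280 lower. As the files hold counts, the pseudocount alternative was not run. The numbers of the block do not pair the libraries, since same-numbered libraries correlated at -0.031, -0.24, -0.095 and -0.052 and none correlated best with its own number. With intron reads, log2 fold changes reversed, none past the threshold, for Ndufv3 (-0.51), Uqcrc1 (-0.30), Echs1 (-0.38), Elovl6 (-0.039), Hmgcs1 (-0.061), Fdps (-0.87), Rps26 (-0.49), Ier3 (-0.052), Gclm (0.0031), Lyz2 (-1.27), Lck (-0.22), Col1a2 (-0.11) and Procr (0.18), and with exon plus intron reads for Elovl6 (-0.039), Lck (-0.083) and Procr (0.051); the cause was not tested. Uncalled genes near 0 also changed sign when single libraries were left out: Lck (-0.088 to 0.15), Il6ra (-0.041 to 0.35), Cd48 (-0.62 to 0.31) and Procr (-0.15 to 0.0060). With the Y-linked covariate and in the libraries with Y-linked reads, Procr (0.097, 0.098), Ddx3y (0.11, 0.11), Uty (0.16, 0.16) and Kdm5d (0.089, 0.089) changed sign; the Y-linked genes did so because libraries without those reads were set apart or removed. Leaving out single libraries also ended the calls of Uqcrc1 and Rplp0 (4-week replicates 1 and 4) and Fdps (P5 replicate 3), and Cdk1, Cs and Sdhd were called without 4-week replicate 2. Depth limits genes with few reads, such as those of class II.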

Other observations

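Tests of the microRNA sites were written before their results were seen. Genes named here were chosen after their values were seen, except those named in the comparison of ages.

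Imprinted RNAs without an mRNA model were higher at P5 as well. By gene reads, H19, the RNA next to Igf2, had a log2 fold change of 3.03 (SE 0.297, adjusted p = 0.000212). The RNAs of the Dlk1 locus Meg3, Rian and Mirg had 1.89, 2.07 and 2.09 (adjusted p = 0.00329, 0.00076 and 0.0293). Among the fetal genes, Lin28b, the inhibitor of let-7 processing, was 5.07-fold higher, with 39.2 ± 3.36 CPM at P5 and 7.70 ± 2.62 at 4 weeks (SD, n = 4 each; adjusted p = 6.06e-06). Arid3a, a transcription factor, was 2.23-fold higher (adjusted p = 2.64e-05), and Plagl1, an imprinted zinc finger gene, 4.35-fold higher with overlap between the ages (adjusted p = 0.00944), with 202 of its 417 P5 reads in replicate 3 and a log2 fold change of 1.496 without that library. Malat1 and Neat1, nuclear RNAs, were lower, by log2 fold changes of -0.70 and -1.504 (adjusted p = 0.0028 and 0.000239). Of the interferon genes without a model, Mx1 was lower at -1.07 (adjusted p = 0.0453) and Mx2 had -0.20 (adjusted p = 0.606). The 13 mRNAs encoded in the mitochondrial genome ranged from -0.31 to 0.35, and edgeR called 0 of them, with 3 at an unadjusted p under 0.05.

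Of the genes of class II antigen presentation, the pathway of professional antigen-presenting cells, 5 picked after their values were seen were many times lower at P5. The list's other class II members, H2-DMa and H2-DMb1, were lower too, as were all 22 members when adjusted over the list alone. H2-Aa had 0.901 ± 0.767 CPM at P5 and 15.8 ± 7.05 at 4 weeks (SD, n = 4 each; adjusted p = 0.000142), and Cd74, the invariant chain, 8.23 ± 1.34 and 52.0 ± 23.2 (SD, n = 4 each; adjusted p = 2.97e-05). H2-Eb1, H2-Ab1 and their transactivator gene Ciita were 20.2-fold, 5.65-fold and 6.30-fold lower, and all 5 genes separated the ages in every library. The call for Ciita was lost with the Y-linked covariate, and leaving out 1 P5 library moved the folds of H2-Aa, H2-Eb1 and Ciita by over 1.5 times. Cdh5, VE-cadherin, had 285 reads over the P5 libraries and 1 over the 4-week libraries, a ratio of 266 (exact 95% interval 47.4 to 10600). The progenitor gene Flt3 was 1.56-fold higher at P5, and Cdkn2c, the inhibitor p18, was 5.73-fold lower. The call for Flt3 was lost when single libraries were left out. Targets of Notch and BMP signalling, Hes1 and Id1, were 2.76-fold and 2.59-fold higher at low levels of 3.40 and 8.04 CPM at P5, and these calls were lost under several alternatives.

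Since Lin28b was higher at P5, a hypothesis was that let-7 acts less there and that genes with its site are higher. Of 12013 genes with a 3' UTR, 441 held the 8-base site CTACCTCA, of which 42 (9.5%) were higher and 30 (6.8%) lower at P5, against 7.9% and 8.6% of genes without it. Their median log2 fold change, matched on UTR length, was 0.014 above that of other genes, at percentile 89 of 419 control words, below the 95th percentile set in advance. Exon minus intron change, which would point to RNA stability, lay 0.035 above, at percentile 88.5. Igf2bp1, Igf2bp3, Hmga2, Lin28b and Igf2bp2 all carry the site and were higher, and the shares above lean the same way, but the shift of the site genes as a set stayed short of the level set in advance, so these tests give no evidence of a broad effect that may be expected of lower let-7 activity.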
